A study of Rattus norvegicus with 12 samples.

How the data were processed

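Total RNA of the livers of 12 adult male Wistar rats, 6 on a 14% casein diet and 6 on a 5% casein diet for 4 weeks, was labelled with Cy3 and hybridised to Agilent single-colour arrays, 1 rat per array, per the labels. Per the file headers, the authors processed the scanned images with Agilent Feature Extraction 12.0.3.1, which found the spots, subtracted background and removed spatial trends. The deposited scanner files hold processed, median and local background intensity on a linear scale, not normalized between arrays. The deposited value table of the series equals the median intensity of each scanner file at 100% of its spots, so it is raw, neither background-subtracted nor scaled. Its column medians were 51.5 to 65.5, and 0 of its columns were left without a sample. Groups and rat numbers were taken from the labels. Nothing in them says that a number links a control rat to a low protein rat.

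The files hold no gene name column, so genes were named through the unversioned RefSeq accession of each probe, matched to a table of the GRCr8 assembly. Of 45598 probes, 21215 (46.5%) matched, to 16667 genes; the others were tested under their own name in the file and are not named in the text. The headers name another genome build, so no coordinates are given. The planned design named genes by the file's gene name, which this replaced.

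Values were log2 of the processed signal less the 75th percentile of each array, over 58717 spots that were not controls. Between 453 and 739 spots per array had an outlier mark and were set missing, no spot was saturated, and spots of a probe were averaged. The coefficient of variation of replicated probes was 3.56% to 4.47%. The SD of negative control spots was 1.11 to 1.32 (mean 1.19) on control arrays. On low protein arrays it was 1.18 to 1.58 (mean 1.43), and the effect of this difference on dim spots was not tested. Probes were kept where they were well above background on at least 5 of 6 arrays of a diet, and 1 probe per gene, that with the highest mean over the 12 arrays, was tested. This left 21858 genes, 11389 of them with a symbol. A filter on brightness removes the noisiest spots, and a gene near background has its fold compressed or made uncertain. The processed signal has small positive values in place of those at background, so folds against dim spots rest on that floor.

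Differences, low protein minus control, were tested with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 with Benjamini-Hochberg adjustment over all genes, at an adjusted p under 0.05. Every adjusted p in the text comes from limma unless another test is named. Tables and figures were made with data.table (version 1.17.8), Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. At least 4 genes were measured in 44 of 47 gene lists. For these, limma's camera compared each list with all other genes at a preset correlation of 0.01. It did so again with the correlation estimated from the residuals. Fry tested whether a list's genes shift in a common direction with diet, without comparing them with other genes. Of the other 3 lists, those of neutrophils and adipocytes have counts only. The lists, the 15 focus genes, the tests and the alternatives were fixed before the data were examined. The genes named were the 8 largest rises and 8 largest falls among changed genes with a symbol (no accession, clone or placeholder name) whose groups did not overlap, the focus genes, and per list up to 4 changed members with the smallest adjusted p, or up to 2 with the smallest p where none changed. This rule gave 126 genes, of which 4 are not reported here, and the alternatives were run for each of the other 122.

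On simulated data with 200 of 21858 genes changed and 6 arrays per group, for the comparison of low protein with control, 59.7% of 1.5-fold, 86.6% of 2-fold and 97.0% of 4-fold changes were recovered. Of the simulated calls 5.17% were false, and camera called 0 of 100 unchanged lists beside 1 list simulated as shifted. The simulated arrays were drawn without correlation between genes.

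Alternatives covered background correction, scaling, the deposited values, the filter on dim probes, outlier spots, probes per gene, the spread estimate, slide, scan and rat number as blocks, each array left out, stricter thresholds and other set tests. The files hold no mean signal column, so normexp with an offset of 50 was run on the median signal; this substitute, fits within each slide, an exact permutation test of list shifts and 4 further gene lists were chosen after seeing the data. Slide and scan coincide, so they give the same fit. On slide 1 the control arrays lay in row 1 and the low protein arrays in row 2, in the same 4 columns. On slide 2 all arrays lay in row 1, the control arrays in columns 1 and 2 and the low protein arrays in columns 3 and 4. Urine, plasma and metabolite data and the PCR measurements were not analysed here.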

Results

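Liver RNA of 12 adult male Wistar rats was measured on single-colour microarrays, with 1 rat on each array. For 4 weeks, 6 rats had eaten a control diet with 14% casein as its protein and 6 had eaten a diet of the same energy content with 5% casein, called low protein below. The arrays served to look at liver enzymes of the metabolites that answer to protein undernutrition. The metabolite measurements of the study were not analysed here. Each array held 58717 spots that were not controls, of which 61.2% to 69.9% were well above background, and its 75th percentile of signal lay between 942 and 1317 intensity units. The number of arrays limits the precision, and the median standard error of a log2 difference was 0.13. Pearson correlations of all gene values across genes were 0.987 to 0.992 between control arrays, 0.985 to 0.990 between low protein arrays and 0.981 to 0.987 between the diets. The arrays lay on 2 slides, each scanned as its own batch, with 4 control and 4 low protein arrays on slide 1 and 2 of each on slide 2. Slide 2 held control rats 2 and 4 and low protein rats 5 and 6, and slide 1 held the others. The diets thus differ in rat number within each slide, and values given by slide carry this difference too.

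**Figure D1:**
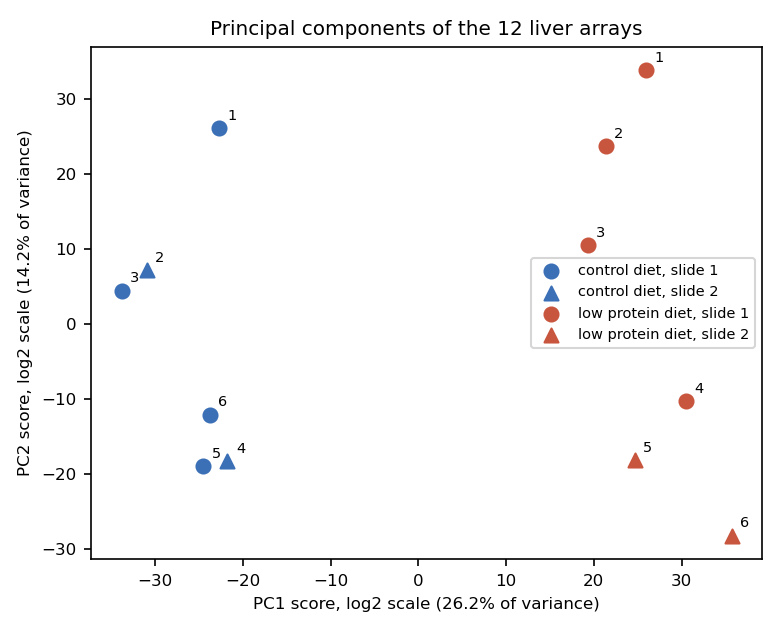
Scores of the 12 arrays on the first and second principal components of the log2 gene values (26.2% and 14.2% of the variance), with colour for the diet, marker shape for the slide and the rat number beside each point. All 6 control arrays lie at negative PC1 scores and all 6 low protein arrays at positive ones. In both diets rats 1, 2 and 3 have positive PC2 scores and rats 4, 5 and 6 negative ones, and the cause was not tested.

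Transcripts of the enzymes that make serine and asparagine were many times more abundant in the livers of low protein rats, and those of serine dehydratase, which breaks serine down, many times less abundant. Phgdh, the first enzyme of serine synthesis, rose 121-fold (log2 change 6.92 ± 0.30, SE, n = 6 rats per diet, adjusted p = 1.4e-07). Asns, which makes asparagine, rose 26.8-fold (4.75 ± 0.35, adjusted p = 1.25e-05), and Fgf21, a liver hormone, rose 17.1-fold (4.09 ± 0.38, adjusted p = 0.000111). Sds, serine dehydratase, was 36.5-fold lower (-5.19 ± 0.74, adjusted p = 0.00194). Transcripts of tRNA synthetases were also higher. With a preset correlation between genes, but not with an estimated one, ribosomal proteins were higher too, and several lists of genes of amino acid degradation and those of fatty acid and cholesterol synthesis were lower.

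Probes without a gene symbol or with a placeholder name are not ranked here, and the largest rise and fall of any changed probe were 7.14 and -5.61. Among genes with a symbol whose 6 low protein values all lay on the same side of the 6 control values, the largest other rises were in Adm2, a peptide hormone of the calcitonin family (42.0-fold, log2 5.39 ± 0.26), Psat1, the next enzyme of serine synthesis (19.6-fold), Colq (14.8-fold), the mitochondrial folate enzyme Mthfd2 (14.0-fold) and the cystine transporter Slc7a11 (13.8-fold). Colq and Slc7a11 were well above background on 3 of the 6 control arrays, so their folds rest in part on dim spots. After normexp, whose offset compresses dim spots, the log2 changes were 3.45 for Adm2, 1.17 for Colq (from 3.89) and 1.34 for Slc7a11 (from 3.78), and in the deposited values those of Colq and Slc7a11 were 1.98 and 2.17. The largest other falls among such genes were in the lectin-like genes Clec2d2l1 (-4.90 ± 0.47) and Clec2d2l2 (-4.77 ± 0.43), in Inmt, an indole and amine methyltransferase (-4.03 ± 0.54), the lipid droplet protein Pnpla3 (-3.69 ± 0.68), the taurine transporter Slc6a6 (-3.43 ± 0.28), Plekhd1 (-3.42 ± 0.62) and Pnpla5 (-2.53 ± 0.34). Clec2d2l1, Clec2d2l2 and Plekhd1 were well above background on 2, 3 and 4 of the 6 low protein arrays. Their values were -2.00, -2.01 and -1.72 after normexp and -2.67, -2.67 and -2.13 in the deposited values, so their ranks depend on the background correction. Clec2d2l1 and Clec2d2l2 are related sequences, and their values were nearly equal on each control array (-3.93 and -3.88 in control rat 1, -1.76 and -1.72 in control rat 5). Their falls may thus be 1 signal read by both probes, and whether the probes share targets was not tested. On slides 1 and 2 taken alone, the log2 changes were 6.71 and 7.33 for Phgdh, 4.66 and 4.92 for Asns, 3.79 and 4.70 for Fgf21, -6.01 and -3.54 for Sds, and -3.38 and -3.52 for Slc6a6.

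**Figure D2:**
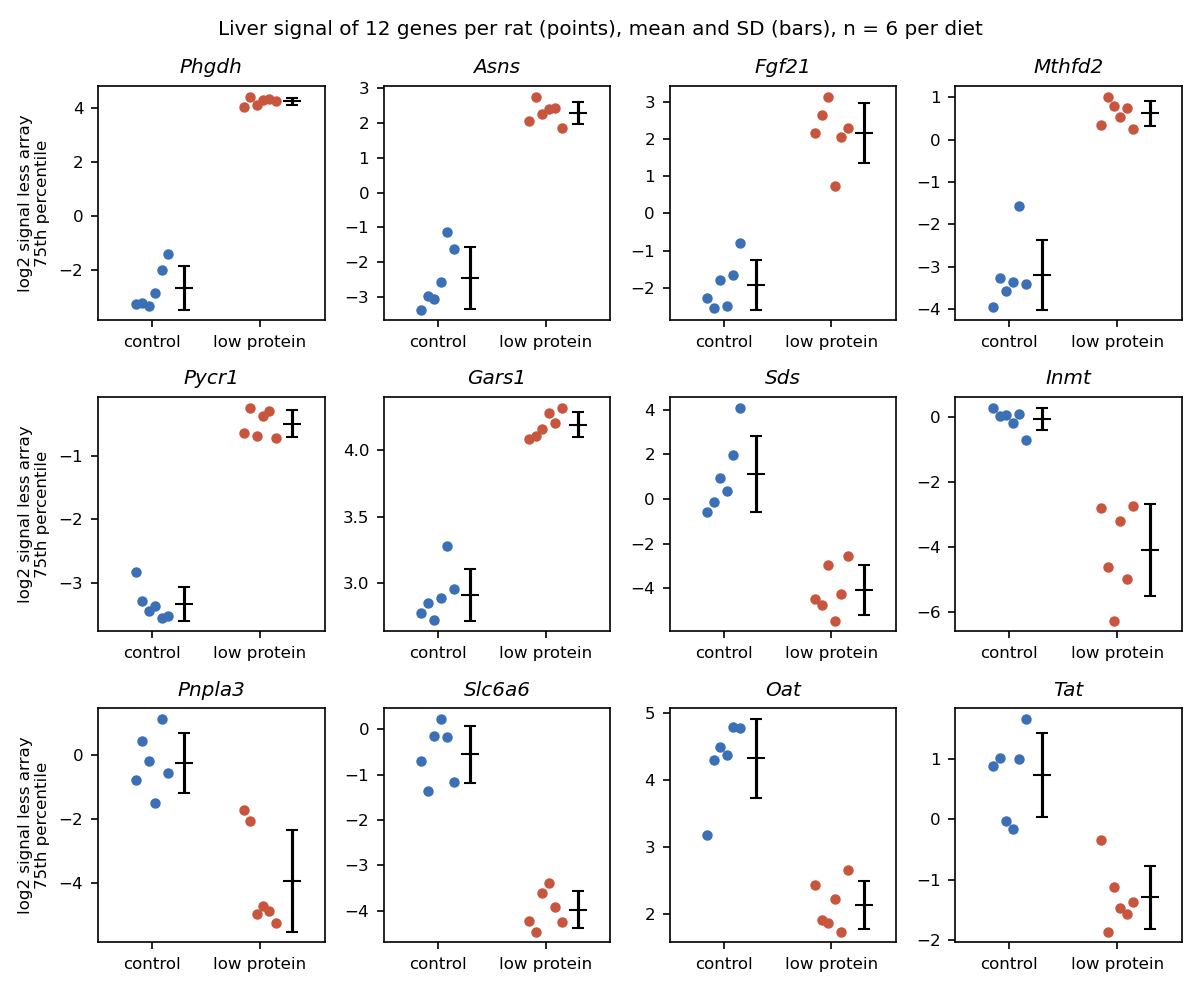
Log2 signal of 12 genes less the 75th percentile of the array, 1 point per rat, with the mean and SD of each diet (n = 6) drawn as a bar beside the points, and the place of a point within its column has no meaning. The groups do not overlap in any panel, and the widest gap is that of Phgdh, with a log2 change of 6.92.

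Of 21858 genes tested, 1428 (6.53%) changed at a limma adjusted p under 0.05, 761 higher and 667 lower in low protein livers. At an unadjusted p under 0.05 there were 4720, and list counts at an unadjusted p below are to be set against that share. A change of at least 2-fold was seen in 247 of the changed genes, 113 higher and 134 lower. The values of the diets did not overlap in 1090 of all tested genes (4.99%), against 0.216% expected by chance, and 902 of these were among the changed genes. With slide as a block 1491 genes changed, and within slide 1 and slide 2 alone 164 and 12 did. Without control rat 3 the count was 856 (442 higher, 414 lower). The balance of rises and falls depended on the scaling between arrays: 53.3% of changed genes were higher in the main setting, 76.2% (680 higher, 212 lower) without scaling and 81.2% (1043 higher, 242 lower) in the deposited raw values, where the median of all genes moved by 0.13 and 0.12 on the log2 scale. After quantile normalization 47.4% were higher (781 higher, 866 lower). Falls also outnumbered rises without control rat 6 (568 higher, 704 lower), low protein rat 1 (543 and 563) or low protein rat 2 (493 and 495).

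All but 1 of the 7 measured genes of non-essential amino acid synthesis rose, and none fell, over all genes and adjusted over the list alone. Besides Phgdh and Asns, Pycr1 (2.83 ± 0.13) and Aldh18a1 (2.99 ± 0.22), which make proline, were among them. The 2 probes of Aldh18a1 gave 1.04 and 2.99, and after normexp its value was 1.26. The list had an adjusted p of 4.94e-17 by camera, a test of a list against all other genes with a preset correlation, and an adjusted p = 0.00124 with an estimated correlation. Its median log2 change was 3.22 on slide 1 and 2.81 on slide 2. Of 21 targets of ATF4, the transcription factor of the amino acid response, 12 rose and none fell (13 adjusted over the list alone), among them the translation repressor Eif4ebp1 (1.25 ± 0.08) and Slc3a2 (1.88 ± 0.13), a subunit shared by several amino acid transporters. This list passed with camera adjusted p = 2.57e-14 and adjusted p = 0.0473 with an estimated correlation, and its medians on the slides were 0.98 and 0.70. Several members also stand in the lists of amino acid synthesis and of transporters, and Cars1 also in that of tRNA synthetases.

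Of the 15 cytosolic tRNA synthetases, 11 rose and none fell (13 adjusted over the list alone), led by Gars1 (1.28 ± 0.09), Mars1 (0.98 ± 0.09), Lars1 (0.92 ± 0.09) and Sars1 (0.78 ± 0.09). The list's camera adjusted p was 4.2e-18, with adjusted p = 0.0337 with an estimated correlation and slide medians of 0.66 and 0.70. Smaller rises were seen in cytosolic ribosomal proteins, with 7 of 24 higher (15 adjusted over the list alone), such as Rpl4 (0.36 ± 0.06) and Rpl6 (0.34 ± 0.07). Camera gave that list an adjusted p of 6.36e-11, but adjusted p = 0.245 with an estimated correlation, and its slide medians were 0.21 and 0.16. None of the 17 ER chaperones and genes of the unfolded protein response passed limma's test, over all genes or adjusted over the list alone, and 3 had an unadjusted p under 0.05. Dnajb9 was at 0.54 (adjusted p = 0.14) and Calr at -0.38 (adjusted p = 0.176). The camera adjusted p of that list was 0.0631, and it was 0.0244 without control rat 2, 0.0207 without control rat 3, 0.0435 without control rat 6, 0.0307 without low protein rat 1, 0.00686 without low protein rat 3, 0.00664 on slide 2 alone and 0.0039 after normexp background correction.

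**Figure D3:**
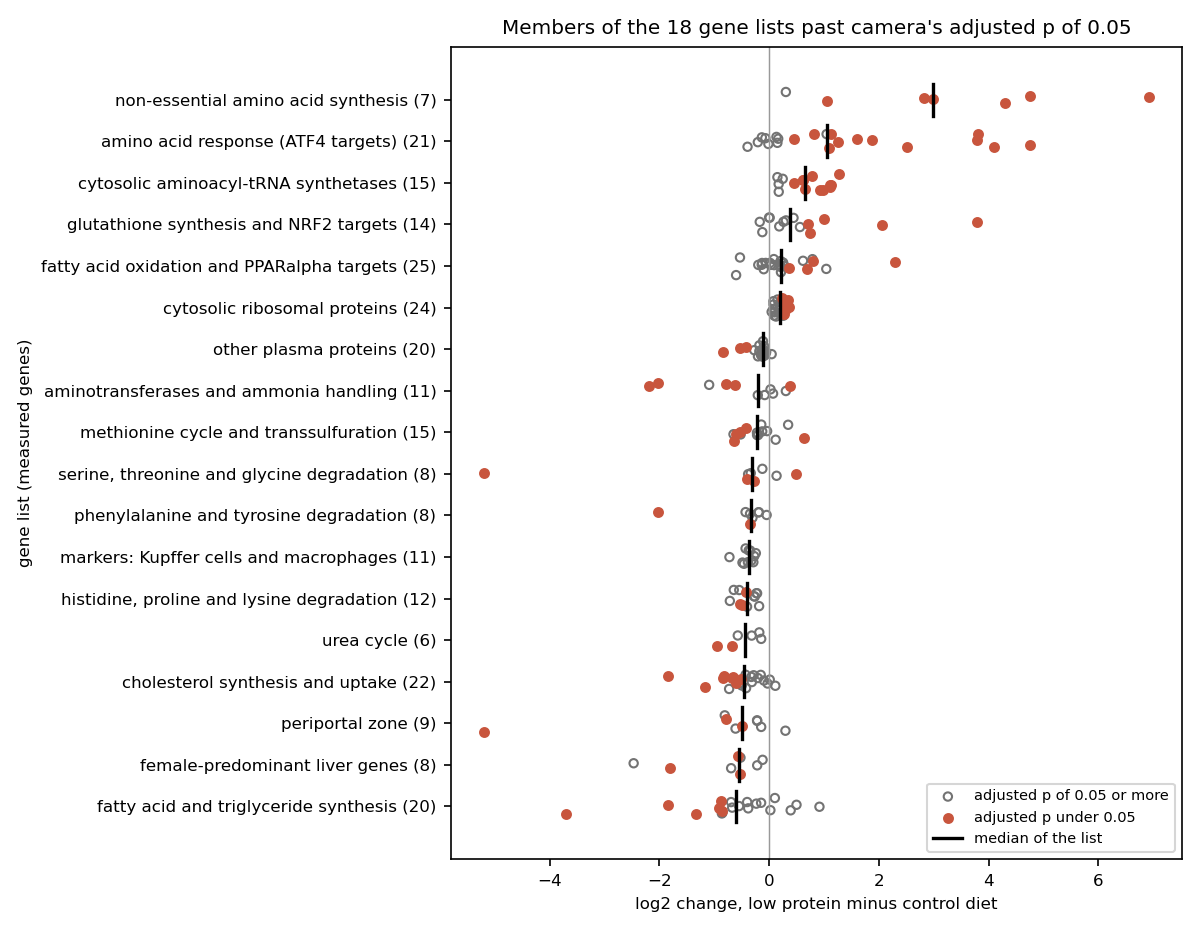
Log2 change, low protein minus control, of each measured member of the 18 gene lists past a camera adjusted p of 0.05 with the preset correlation; filled points are genes past a limma adjusted p of 0.05, open points the others, black bars the list medians. The medians of 6 lists lie above 0 and those of 12 below. With an estimated correlation 3 lists also pass, those of amino acid synthesis, ATF4 targets and tRNA synthetases. Of these, the ATF4 list shares Asns with the first and Cars1 with the last.

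Several lists of enzymes that break amino acids down passed as lower by camera with the preset correlation, but not with an estimated one. Fry, which does not set a list against other genes, called them lower too. Its adjusted p was 0.00167 for the urea cycle, 0.00167 for phenylalanine and tyrosine and 0.000104 for histidine, proline and lysine. It was 0.0133 for aminotransferases and ammonia handling and 0.0163 for serine, threonine and glycine. In the urea cycle, Cps1 (-0.68 ± 0.14) and Ass1 (-0.95 ± 0.20), 2 of 6 measured genes, fell and none rose (4 adjusted over the list alone, camera adjusted p = 0.000498, adjusted p = 0.154 with an estimated correlation). Of 8 genes of phenylalanine and tyrosine degradation 2 fell, Tat, tyrosine aminotransferase (-2.02 ± 0.32), and Qdpr (-0.34 ± 0.07), and 6 did adjusted over the list alone (camera adjusted p = 0.000116, adjusted p = 0.19 with an estimated correlation). Histidine, proline and lysine degradation had 3 of 12 genes lower, with Aldh4a1 at -0.53 ± 0.07 and Aldh7a1 at -0.42 ± 0.06, and 11 adjusted over the list alone (camera adjusted p = 9.84e-08, adjusted p = 0.0532 with an estimated correlation). Slide medians were -0.48 and -0.38 for the urea cycle, -0.28 and -0.32 for tyrosine and -0.46 and -0.31 for histidine, proline and lysine.

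Among 11 aminotransferases and genes of ammonia handling, 4 fell and 1 rose (5 and 1 adjusted over the list alone). Ornithine aminotransferase Oat (-2.18 ± 0.26) and the liver glutaminase Gls2 (-0.79 ± 0.13) fell with Tat, and Glud1 (0.39 ± 0.09), glutamate dehydrogenase, rose. The camera adjusted p was 0.0223, adjusted p = 0.345 with an estimated correlation, 0.0515 after normexp, 0.0543 without control rat 6, 0.0597 without low protein rat 3 and 0.416 on slide 2 alone. Slide medians were -0.29 and -0.30. In serine, threonine and glycine degradation 3 of 8 genes fell and 1 rose (4 and 1 adjusted over the list alone), with Sdsl, a relative of Sds, at -0.41 ± 0.09 and slide medians of -0.32 and -0.27. That list's camera adjusted p was 0.034, adjusted p = 0.39 with an estimated correlation, 0.0727 after normexp, 0.0601 without control rat 1, 0.057 without low protein rat 3, 0.0798 without low protein rat 5, and 0.0682 and 0.109 on slides 1 and 2. Periportal genes, which overlap these lists in Sds, Gls2 and others, had 3 of 9 lower (7 lower and 1 higher adjusted over the list alone), with camera adjusted p = 0.000415, adjusted p = 0.0532 with an estimated correlation and slide medians of -0.30 and -0.45. Of 9 pericentral genes, Oat fell (1 also adjusted over the list alone, camera adjusted p = 0.848).

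The 15 focus genes, chosen for the metabolites and hormones of the design before the data were examined, included 7 that passed, 3 higher and 4 lower, and 11 adjusted over the list alone. In taurine synthesis, the cysteine dioxygenase Cdo1 fell (-0.69 ± 0.15, adjusted p = 0.017) and the decarboxylase Csad rose (0.89 ± 0.16, adjusted p = 0.00761), beside Cps1, Sds, Tat, Asns and Fgf21 above. On slides 1 and 2 alone Cdo1 was at -0.62 and -0.83 and Csad at 1.00 and 0.66. The call for Cdo1 ended without scaling (adjusted p = 0.128), in the deposited values (0.0654) and without the filter on dim probes (0.0504). Fmo1, a flavin monooxygenase, was at 0.59 ± 0.17 (adjusted p = 0.0592) and the growth factor Igf1 at -0.33 ± 0.10 (adjusted p = 0.0627, its 5 probes gave -0.89 to -0.21). Fmo1 passed without control rat 2 (adjusted p = 0.04998), without scaling, in the deposited values, after normexp and with the trended robust spread, and Igf1 without low protein rat 3 (adjusted p = 0.0198), after quantile normalization, after normexp, with the trended robust spread and as the mean of its probes. Nnmt, which methylates nicotinamide, was at -0.60 ± 0.20 (adjusted p = 0.10), with -0.89 on slide 1 and -0.02 on slide 2. The rat numbers of the diets differ within each slide, as given above, so these values are not a plain repeat of each other. Values further below the threshold were -0.20 for Bhmt, 0.10 for Chdh, 0.12 for Gatm and 0.04 for Gamt. That of Gamt turned sign under another scaling (-0.05 after quantile normalization).

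**Figure D4:**
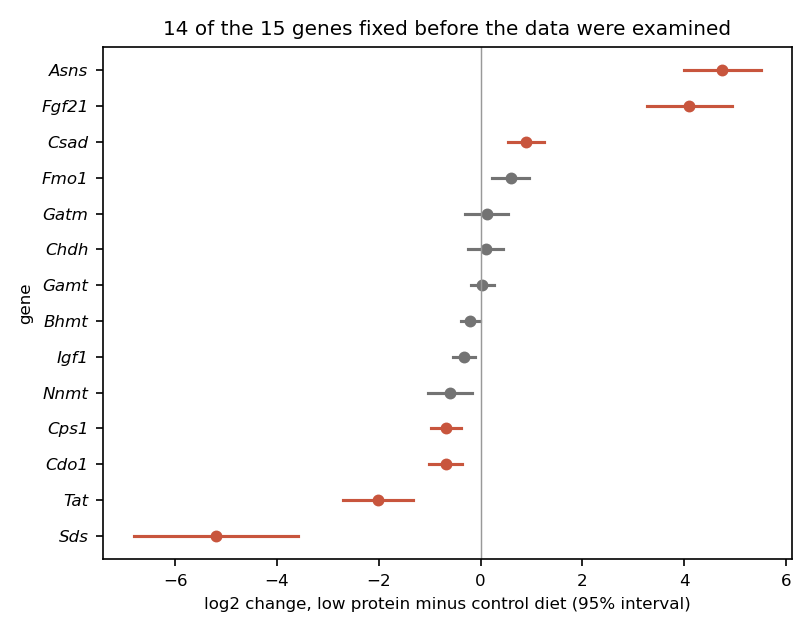
Log2 change, low protein minus control, of 14 of the 15 focus genes with confidence intervals from limma, red where the adjusted p is under 0.05 and grey otherwise. Asns (4.75) and Fgf21 (4.09) lie farthest right, Sds (-5.19) and Tat (-2.02) farthest left.

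The lists around these metabolites held changes in both directions. In the methionine cycle and transsulfuration 4 of 15 genes fell and 1 rose (6 and 2 adjusted over the list alone). Sulfite oxidase Suox (-0.64 ± 0.08) and the sulfide oxidase Sqor (-0.54 ± 0.09) fell and methionine synthase Mtr (0.64 ± 0.13, or 0.25 after normexp) rose. Camera gave an adjusted p of 0.0111, with adjusted p = 0.39 with an estimated correlation, 0.0541 on slide 2 alone, and slide medians of -0.18 and -0.32. The taurine list had 1 gene higher and 2 lower of 6 (3 and 2 adjusted over the list alone, camera adjusted p = 0.954), and its median of 0.10 and mean of -0.41 differed in sign, with Slc6a6 at -3.43. Choline, betaine and trimethylamine oxidation had 1 of 16 higher, Fmo5 (1.69 ± 0.30), and 2 lower, Aldh7a1 and Dmgdh (-0.46 ± 0.09), with camera adjusted p = 0.965 and 2 each way adjusted over the list alone. None of 5 creatine genes passed limma's test, over all genes or adjusted over the list alone, 1 had an unadjusted p under 0.05, and camera's adjusted p was 0.954. Ckb was at -0.31 and Slc16a12 at 0.47, and Ckb passed without control rat 6 (adjusted p = 0.0457). Of 13 amino acid transporters, Slc3a2 rose and Slc16a10 (-1.83 ± 0.23) and Slc38a4 (-0.76 ± 0.12) fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.948). Tryptophan, kynurenine and nicotinamide genes had 2 of 15 lower, Acmsd (-1.25 ± 0.25) and Aadat (-0.45 ± 0.10), with 5 lower and 2 higher adjusted over the list alone. The camera adjusted p was 0.0818, and 0.0362 without control rat 4 and 0.0414 without low protein rat 2. It was 0.044 after quantile normalization, 0.0242 in the deposited values and 0.00372 without the filter on dim probes. In branched-chain amino acid degradation 1 of 18 genes fell, Ivd (-0.44 ± 0.09), and 1 rose (3 and 2 adjusted over the list alone, camera adjusted p = 0.848).

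Lists of lipid synthesis passed as lower by camera with the preset correlation, but not with an estimated one. Fry gave an adjusted p of 0.00947 both for fatty acid and triglyceride synthesis and for cholesterol synthesis and uptake. Of 20 genes of fatty acid and triglyceride synthesis 6 fell and none rose (10 lower and 1 higher adjusted over the list alone), including Acacb, an acetyl-CoA carboxylase (-1.33 ± 0.13, or -0.68 after normexp and -0.78 in the deposited values), Elovl5 (-0.85 ± 0.11), Fads1 (-0.87 ± 0.12) and Pnpla3. Camera gave this list an adjusted p of 5.02e-05, with adjusted p = 0.345 with an estimated correlation, and slide medians were -0.31 and -0.71. In cholesterol synthesis and uptake 8 of 22 genes fell and none rose (13 adjusted over the list alone), such as the sterol carrier Stard4 (-0.66 ± 0.10), Lss (-0.85 ± 0.13), Pmvk (-1.17 ± 0.21) and Cyp51 (-0.82 ± 0.16). Its camera adjusted p was 1.31e-07, with adjusted p = 0.245 with an estimated correlation, and slide medians were -0.39 and -0.52. Fatty acid oxidation and PPARalpha targets had 4 of 25 genes higher and none lower (6 adjusted over the list alone), with the pantetheinase Vnn1 (2.29 ± 0.33), Cpt2 (0.69 ± 0.12, with 1.07 on slide 2) and Hadhb (0.36 ± 0.08). That list's camera adjusted p was 0.00129, with adjusted p = 0.245 with an estimated correlation, and slide medians were 0.12 and 0.38. In gluconeogenesis 2 of 7 genes rose (3 higher and 1 lower adjusted over the list alone), led by the mitochondrial Pck2 (1.54 ± 0.14), with camera adjusted p = 0.096, and 0.011 after normexp and 0.0244 over probes well above background on all 12 arrays, and a fry adjusted p of 0.00167. Glycolysis and fructose use had 1 of 14 higher (1 adjusted over the list alone, camera adjusted p = 0.401).

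Of 14 genes of glutathione synthesis and NRF2 targets 5 rose and none fell, also adjusted over the list alone: Slc7a11, both subunits of the first enzyme of glutathione synthesis, Gclm (1.00 ± 0.15) and Gclc (0.74 ± 0.16, with 0.35 on slide 2), and Akr7a3 (2.06 ± 0.35) were among them. Slc7a11 is also an ATF4 target. The camera adjusted p was 0.000298, with adjusted p = 0.245 with an estimated correlation, and slide medians were 0.45 and 0.23. Of 8 liver genes that are higher in females 3 fell and none rose (4 adjusted over the list alone), including Cyp2a1 (-0.54 ± 0.07) and Cyp2c7 (-0.57 ± 0.12), with camera adjusted p = 0.000348, adjusted p = 0.147 with an estimated correlation and slide medians of -0.52 and -0.64. Of 11 male-predominant genes 1 fell, Cyp2a2 (-0.74 ± 0.07), and 1 rose (1 each way adjusted over the list alone, camera adjusted p = 0.88). Xenobiotic metabolism had 3 of 22 lower and 1 higher, the nuclear receptor Nr1i3 (1.01 ± 0.20), with the same counts adjusted over the list alone, and camera adjusted p = 0.965. Plasma proteins outside the acute phase had 3 of 20 lower, with Apoa1 at -0.84 ± 0.14, and none higher (3 adjusted over the list alone, camera adjusted p = 0.000498, adjusted p = 0.502 with an estimated correlation, fry adjusted p = 0.0559, slide medians -0.10 and -0.22).

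Among members named by the same rule, 16 of 84 calls ended when 1 array was left out. The adjusted p without each such array is given as a range. In amino acid use, Hal (-0.50) lost its call without control rats 3 or 4 or low protein rat 2 (0.0517 to 0.0561). Acat1 (0.31) did so without control rat 5 or low protein rats 1, 2, 5 or 6 (0.0502 to 0.0559), and Shmt2 (0.49) did so without control rats 3, 4, 5 or 6 or low protein rats 1, 2, 4 or 5 (0.0511 to 0.0735). Gcsh (-0.28) did so without control rats 1, 2, 3, 4, 5 or 6 or low protein rats 2, 3, 4 or 5 (0.0535 to 0.0898), and Bhmt2 (-0.42) did so without control rats 2, 3, 4, 5 or 6 or low protein rats 1, 3 or 5 (0.0508 to 0.0827). Of the ribosomal proteins named, Rps6 (0.27) did so without control rat 3 or low protein rats 2 or 5 (0.051 to 0.0524). In energy metabolism, Acot2 (0.80) did so without control rat 3 or low protein rats 3, 4, 5 or 6 (0.05003 to 0.0606). Pc (0.31) did so without control rats 2, 3, 4 or 5 or low protein rats 1, 2 or 4 (0.05003 to 0.0656), and Gpi (0.65) did so without control rats 3, 4, 5 or 6 or low protein rats 1, 2, 4 or 6 (0.0589 to 0.0768). Among cytochromes, Cyp3a9 (-1.20) did so without control rats 1, 3 or 4 or low protein rats 2, 4 or 5 (0.0506 to 0.0581). Cyp3a2 (0.54) did so without control rats 2, 3, 4, 5 or 6 or low protein rats 1, 2, 4 or 5 (0.0516 to 0.0633), and Cyp2c12 (-1.80) did so without control rats 4 or 5 or low protein rats 2, 3, 4, 5 or 6 (0.057 to 0.0673). Of the plasma proteins, Apoa2 (-0.42) did so without control rats 2, 3, 4 or 5 or low protein rats 2, 3, 4 or 5 (0.0515 to 0.0753), and Serpina6 (-0.52) did so without control rats 3, 4, 5 or 6 or low protein rats 2, 3, 4, 5 or 6 (0.0518 to 0.091). The only changed gene of autophagy, Atg12 (-0.28), did so without control rats 2, 3, 4, 5 or 6 or low protein rats 1, 4, 5 or 6 (0.0558 to 0.0914). The only one of the cell cycle, Rrm2 (-1.11), did so without control rats 2, 3, 5 or 6 or low protein rats 1, 2, 5 or 6 (0.066 to 0.0862). Without scaling 22 of the 84 calls ended, in the deposited values 15 and without the filter on dim probes 24, among them Cdo1, Aadat, Ivd, Sdsl, Qdpr, Sqor, Dmgdh, Aldh4a1, Aldh7a1, Glud1, Hadhb, Rpl6, Cyp2a1, Cyp2c7 and Gclc in at least 1 of the 3, and no call turned sign in any setting. In the deposited values Ivd was at -0.26, Sdsl at -0.26, Dmgdh at -0.29, Gcsh at -0.15, Atg12 at -0.11 and Pc at 0.50. Unscaled, Qdpr was at -0.21, Gcsh at -0.14 and Atg12 at -0.15, and after quantile normalization Rps6 was at 0.18. On slides 1 and 2 Acot2 was at 0.53 and 1.33, and on slide 2 Serpina6 was at -0.32.

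Markers of other cell types were given as values. All 11 markers of Kupffer cells and macrophages were below 0 (median -0.37, -0.26 on slide 1 and -0.61 on slide 2), such as Adgre1 (-0.49, adjusted p = 0.111) and C1qa (-0.39, adjusted p = 0.118). None passed limma's test over all genes, 5 did adjusted over the list alone and 8 had an unadjusted p under 0.05. The list's camera adjusted p was 0.000346, with adjusted p = 0.435 with an estimated correlation and a fry adjusted p of 0.0644. Without control rat 6, the adjusted p was 0.023 for Adgre1, 0.0316 for C1qa and 0.00662 for Gzma, a T and NK cell gene at -0.38 (Prf1 was at -0.37). The 9 markers of T and NK cells had a median of -0.29, 0 that passed over all genes or adjusted over the list alone, 2 with an unadjusted p under 0.05, and a camera adjusted p of 0.0809, which was 0.000323 without control rat 6, 0.0346 without low protein rat 4 and 0.0272 without low protein rat 5. It was 0.041 without scaling, 0.0251 in the deposited values, 0.01 without the filter on dim probes, 0.0366 over probes above background on all 12 arrays and 0.0309 on slide 2 alone. The neutrophil genes S100a8 and S100a9 were at 0.34 and 0.35 (1 with an unadjusted p under 0.05), and of 3 adipocyte markers Cidec, a lipid droplet protein, rose (0.74 ± 0.13, adjusted p = 0.0069, 1 adjusted over the list alone). No marker passed limma's test, over all genes or adjusted over the list alone, among 12 of stellate cells (Pdgfrb -0.62, Lrat 0.29, camera adjusted p = 0.706), 10 of endothelial cells (Flt1 -0.23, Cdh5 -0.21, 0.954), 5 of cholangiocytes (Epcam -0.46, Cftr -0.54, 0.401), 6 of erythroid cells (Ahsp 0.30, Alas2 0.22, 0.706) and 4 of exocrine pancreas (Cel 0.65, Cela1 -0.07, 0.708). The counts at an unadjusted p under 0.05 were 1, 2, 2, 0 and 1 for those 5 lists. Over all tested genes this held for 4720 of 21858, so such counts do not by themselves mark a list. Cftr was well above background on 3 low protein arrays and had an adjusted p of 0.0451 without low protein rat 6, and its value was 0.26 with outlier spots kept.

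The remaining lists did not pass camera. Limma called none of 24 proteasome genes (Psmb2 0.17, Psma6 0.19), and 2 of them had an unadjusted p under 0.05 (camera adjusted p = 0.965). It called none of 21 genes of oxidative phosphorylation (Sdha -0.14, Ndufs1 0.14), with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.456). None of 18 genes of bile acid synthesis and transport passed limma's test (Nr1h4 0.36, Hsd3b7 0.24), though Nr1h4 did in the deposited values (0.48, adjusted p = 0.0479), and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.948). The GH and IGF axis had none of 17 past limma's test (Irs1 -0.29, or -0.22 with adjusted p = 0.0474 after normexp, and Igf1 as above), with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.19). Acute phase proteins had none of 16 past it (Crp -0.36, Fgg -0.18), with 0 at an unadjusted p under 0.05 (camera adjusted p = 0.355). None of the 14 clock genes passed limma's test (camera adjusted p = 0.706), and 0 had an unadjusted p under 0.05. Nfil3 was at -1.01, and Per2 was at -0.72, with -1.09 on slide 1 and 0.02 on slide 2. The SD within control and low protein rats was 0.64 and 1.31 for Nfil3 and 0.55 and 0.93 for Per2. With such spread, changes of these sizes could be missed. In these 6 lists no gene passed adjusted over the list alone. Autophagy and lysosome had 1 of 15 lower (1 adjusted over the list alone, camera adjusted p = 0.965), and cell cycle 1 of 19 lower (1 adjusted over the list alone, camera adjusted p = 0.401, and 0.0357 without low protein rat 4). In other settings camera called oxidative phosphorylation after quantile normalization (adjusted p = 0.000889), where Sdha passed too (-0.23, adjusted p = 0.0351), and the GH and IGF axis without the filter on dim probes (0.012, and fry adjusted p = 0.036 in the main setting), where acute phase proteins (0.0467) and the cell cycle (0.0351) passed too.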

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

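The test for a lone array was applied to each diet group of the 122 named genes and of the array measures, 259 groups in all; it divides the gap between the outermost array and its neighbour by the range of the group. Past the limit lay 22 groups, where chance flags about 1 in 20 groups, or 12.9 here. Control rat 1 was the lone array in 6 of them, the most of any array. In that rat Cdo1 (0.909, log2 signal 2.38 against 3.18 to 3.26 in the other controls) and Oat (0.689, 3.18 against 4.29 to 4.79) were low, and Pycr1 (0.641), Stard4 (0.766), Hsd3b7 (0.745) and Akr7a3 (0.701) were high. The Cdo1 and Oat values of this rat lie towards those of the low protein rats, and so do those of Pycr1, Akr7a3 and Hsd3b7. That of Stard4 lies away from them (2.07, against 1.58 to 1.69 in the other controls and 0.86 to 1.23 in low protein rats).

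Other lone control arrays were rat 5 for Mthfd2 (0.71, -1.58 against -3.95 to -3.26), rat 4 for Rpl4 (0.652), rat 2 for Sdha (0.692) and Acot2 (0.678), rat 3 for Cyp2a1 (0.692), and rat 6 for Pdgfrb (0.692) and Gzma (0.715). Among low protein arrays these were rat 2 for Slc7a11 (0.633, -1.34 against -3.51 to -2.71), rat 4 for Sdsl (0.669) and Cdh5 (0.658), rat 3 for Hadhb (0.699) and Nr1i3 (0.638), and rat 1 for Cyp3a2 (0.632) and Cyp2c12 (0.754, 1.32 against -0.98 to -0.42). Of the array measures, the median signal of control rat 4 (0.651, 56.4 against 41.3 to 46.5) and the variation of replicated probes of control rat 2 (0.687, 4.47% against 3.56% to 3.84%) stood apart. No explanation of these single arrays was tested.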

How the results depend on the processing

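A list's value here is its median less the median of all genes in the same setting. None of the 84 called genes or 18 called lists turned sign in any setting: of 2431 values of called genes 2104 stayed past the threshold and 327 did not, and of 540 values of called lists 511 stayed and 29 did not. Of 38 uncalled genes and 26 uncalled lists, 1067 of 1100 and 695 of 778 values kept sign and side. Signal over background limits what is seen: 61.2% to 69.9% of spots were well above it, and folds against dimmer spots are uncertain.

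Without scaling 892 genes changed, with 680 higher and 212 lower. In the deposited values 1285 did, with 1043 higher and 242 lower. Without the filter 618 changed (326 and 292), over 39002 genes. The count was 164 (82 and 82) on slide 1 and 12 (11 and 1) on slide 2, where fewer arrays are fitted, with 4 and 2 focus genes. Leaving out 1 array gave 856 to 1307 genes, 442 to 739 higher and 414 to 704 lower, 7 to 8 focus genes and 17 to 20 lists. At an adjusted p under 0.01 there were 438 (244 and 194), at 2-fold 247 (113 and 134). With an estimated correlation 3 lists passed. The other settings gave 1307 (median scaling) to 1753 genes (trended robust spread).

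Rat number as a replicate block gave 1412 genes (680 higher, 732 lower, 1047 shared), 8 focus genes, with Nnmt added (adjusted p = 0.0264), and 17 lists, without serine, threonine and glycine degradation (0.052). It ended 13 of the 84 gene calls, those of Glud1, Acat1, Gcsh, Hal, Bhmt2, Rps6, Atg12, Hadhb, Pc, Cyp2c12, Apoa2, Serpina6 and Rrm2 (adjusted p 0.0508 to 0.0989). The labels link no numbers, and the rule followed takes numbers as pairs only where each same-number correlation of deviations is over 0.1. Here 5 of 6 were, so the block was kept as an alternative, though the values lean towards a link (0.0338 to 0.259, mean 0.127 against -0.0252 for different numbers, exact one-sided p = 0.0208). Of the arrays, 2 of 6 of each diet correlated best with their own number.

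Values that turned sign all belong to uncalled genes and lists, and the cause was not tested. Those of Cftr (-0.54), Per2 (-0.72) and the cholangiocyte list (-0.247) were farthest from 0 in the main setting. After normexp they were branched-chain degradation 0.00819, choline 0.00926, proteasome 0.0224 and male genes 0.0164. After quantile normalization they were Gamt -0.0474, glycolysis -0.00227, bile acid -0.0335, male genes 0.0481 and pancreas -0.00672. Without scaling: Cela1 0.0653. Deposited values: Cela1 0.0725, pericentral 0.000315 and stellate 0.000878. Without the filter: creatine -0.0256, autophagy -0.0192, glycolysis -0.0494, bile acid -0.0706, endothelial -0.0191 and pancreas -0.0507. Outlier spots kept: Cftr 0.26. Mean of probes: stellate 0.00329 and pancreas -0.0011. Array weights: stellate 0.00942. Slide 1: autophagy -0.0123, male genes 0.00588 and endothelial -0.0352. Slide 2: Gatm -0.15, Gamt -0.0249, Per2 0.0162, Cftr 0.32. Lists there were choline 0.17, creatine -0.11, transporters 0.13, proteasome 0.0148, bile acid -0.0081, clock 0.0949, pericentral 0.0599, stellate 0.112, endothelial -0.0632 and cholangiocytes 0.353. Without 1 array in turn the ranges were Chdh -0.0035 to 0.17, Gamt -0.0224 to 0.0613, Cela1 -0.12 to 0.029. For lists they were choline -0.0893 to 0.0233, proteasome -0.0282 to 0.0249, oxidative phosphorylation -0.0398 to 0.00714, glycolysis -0.0351 to 0.0922, bile acid -0.0415 to 0.0388, male genes -0.0538 to 0.0223, clock -0.141 to 0.0157, pericentral -0.148 to 0.0137, stellate -0.0912 to 0.0163 and pancreas -0.0137 to 0.0529.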

Other observations

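The 4 gene lists of this paragraph and the next were written after the values had been seen, and some members were already known to be called, so they are descriptions and not independent evidence. Genes of ribosome biogenesis, which process ribosomal RNA and assemble its subunits, were higher in low protein livers, 27 of 33 measured, such as Nop16 (0.54 ± 0.07), Ebna1bp2 (0.62 ± 0.08), Pwp2 (0.73 ± 0.11) and Gar1 (0.88 ± 0.16). The list's median was 0.46 (0.45 on slide 1 and 0.51 on slide 2), with camera adjusted p = 6.64e-25 and adjusted p = 0.0172 with an estimated correlation. Of its 27 calls, 12 ended on leaving out at least 1 array (adjusted p up to 0.1001, for Nolc1 without control rat 3). Purine and pyrimidine synthesis had 9 of 17 genes higher, among them Ctps1 (1.19 ± 0.12) and Paics (0.52 ± 0.07), with a median of 0.37, camera adjusted p = 1.99e-10 and adjusted p = 0.000808 with an estimated correlation, and 3 of its 9 calls ended in the same way (up to 0.0758).

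Of 12 genes of the folate one-carbon cycle 4 rose, led by the mitochondrial enzymes Mthfd2 (3.81 ± 0.32) and Mthfd1l (2.07 ± 0.22), with camera adjusted p = 0.00576 and adjusted p = 0.0347 with an estimated correlation. The other 2 calls, of Shmt2 and Mthfd1, ended on leaving out at least 1 array (up to 0.094). Interferon-stimulated genes were lower, 10 of 23 measured, with Oas1a at -0.80 ± 0.17 and Mx1 at -0.63 ± 0.13; the median was -0.35 (-0.28 and -0.40 on the slides), with camera adjusted p = 1.53e-07 and adjusted p = 0.0535 with an estimated correlation. The other 8 calls of that list each ended on leaving out at least 1 array (up to 0.1082). Markers of Kupffer cells and of T and NK cells had medians of -0.37 and -0.29 and were lower on slide 2 than on slide 1 as well. Control rats 5 and 6, the lowest controls in Adgre1, C1qa and Prf1, were on slide 1 only, so the slide difference depends on which rats each slide held. Whether the interferon genes follow the number of such cells was not tested.

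Of the tests below, those on other splits of the arrays and the comparison of same-slide with other-slide pairs were fixed before their values were seen, and the others were chosen after the result was seen. The difference between diets could come from the position of the arrays, since slide 1 held the diets in separate rows and slide 2 in separate columns of the same row. Of the genes called on slide 1, 98.17% had the same sign on slide 2, which an effect of the row alone does not give. The diets share their columns on slide 1, so an effect of the column alone does not give the calls there either. For a row effect on slide 1 joined to a column effect on slide 2, the change from columns 1 and 2 to columns 3 and 4 was taken within each diet on slide 1 over the 1428 changed genes. Its slope over the diet difference on slide 2 was -0.004409 (-0.0456 to 0.0368 without 1 array), where a cause would need about 1. The changed genes were called by a fit that disfavours genes varying within a diet, which by itself pulls this slope towards 0. Columns 1 and 2 also held the lower rat numbers of each diet on slide 1. The slope therefore does not decide on a column effect that is alike on both slides. Over the genes called on slide 1, the slope of the slide 2 difference on that of slide 1 was 0.933. Over all tested genes the differences of the slides correlated at 0.598. A row effect on slide 1 and an unrelated column effect on slide 2 would not give such agreement, so these values argue against that pair. Position effects that change the same genes alike on both slides stay open. Of 100 splits of the 12 arrays into groups of 6, 1 called as many genes as the diets, which was the diet split itself (1428, against 43 at the highest other). For lists the count was 2 of 100: the diets gave 18 and the highest other split 19, and the other 99 splits called a median of 7, so the number of lists called is weak evidence by itself. An exact permutation of list medians over 462 splits, also added after the data were seen, passed 14 lists after adjustment, 13 of them among the 18. The 14th, of endothelial markers (adjusted p = 0.0318), is not called by camera (0.954), and glutathione, methionine, Kupffer cells, other plasma proteins and aminotransferases did not pass.

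No clock gene passed the test between the diets, but rats with the same number in the 2 diets deviated together in these 14 genes. The test counts such shared deviations as noise, so it does not show that diet left these genes unchanged. The mean same-number correlation was 0.762, against -0.146 for different numbers, at percentile 100 of 10000 random lists matched on spread. Those lists were not matched on correlation between genes, so the percentile by itself says little about the numbers. Of 6 arrays per diet, 3 control and 4 low protein arrays correlated best with their own number. Dbp was at 3.71 and 4.00 in the control and low protein rats of number 6 and at -0.33 and -0.51 in those of number 1. Pairings of the 2 diets as high as this made up 5 of 720 (exact p = 0.006944). The slide could produce it: same-slide less other-slide pairs of different number differed by 0.1727, between -0.0256 and 0.391 without 1 array, which leaves that undecided. Same-numbered rats on different slides were above pairs of different number by 0.8337, which the slide does not give. Shared times of sampling for equal numbers might explain it; the labels give no times.

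The rise of ATF4 targets might come from stress of the endoplasmic reticulum or from scaling. The mean of the 17 ER chaperone genes was 0.13, and 0.3343 with 2 standard errors added. The mean of the 21 ATF4 targets was 1.33, so a chaperone rise of like size was not seen. A smaller one stays open: camera called the chaperone list in several settings given above, and its exact permutation p was 0.039 (adjusted 0.0905). The comparison therefore does not exclude such stress. Under quantile, median and no scaling the lowest ATF4 median, with nothing subtracted, was 1.035, against 1.05 in the main setting, so the choice of scaling does not account for it. Whether lack of an amino acid acts through ATF4 in these livers was not tested.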
